A study of Mus musculus with 16 samples.

How the data were processed

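Messenger RNA was measured by stranded, poly(A)-selected RNA sequencing in 16 libraries of cultured mouse articular chondrocytes, 4 libraries in each of 4 groups: vehicle, bleomycin, doxorubicin and interleukin-1 beta (IL-1β). Each deposited table held 1 library and listed 55450 genes by symbol and Ensembl identifier with FPKM values, mapped fragments scaled to gene length and library size, which the authors had computed. Per the submitters' processing notes, reads were trimmed with Trimmomatic and aligned with STAR to the mouse genome build GRCm38, with no versions given. The tool that computed FPKM, its gene annotation and its filters were not given in the sources used here.

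The unit was checked on the values. No column was whole-numbered, no value was negative, and the FPKM sums ranged from 405159 to 423830 in the vehicle, bleomycin and doxorubicin libraries and from 521294 to 559190 in the IL-1β libraries. Depth was estimated from the steps between the lowest FPKM values of genes with a single annotated transcript of at least 1000 bases. It came to 15.7 to 21.9 M fragments (M, mega) per library: 15.7 to 19.2 M in vehicle, 15.7 to 21.9 M in bleomycin, 16.8 to 21.4 M in doxorubicin and 16.6 to 17.2 M in IL-1β. At these depths 1 FPKM on a gene of 1 kilobase stands for 15.7 to 21.8 fragments. Only 55.1% to 58.7% of the low values came out as whole fragments within a tolerance of 0.1, so counts were not recovered and a count test was not run. Identifiers were matched to GENCODE M21, the source of gene coordinates on GRCm38: 54312 identifiers had the same version there and 55104 matched without the version. The tables had 0 rows on the mitochondrial chromosome. Replicates of a group were checked for copied values, and at most 0.009% of the genes with at least 1 FPKM had equal values in a pair of replicates.

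Values were analysed as log2(FPKM + 1), with no further scaling between libraries. Genes with at least 1 FPKM in at least 4 of the 16 libraries were tested, 12976 in number. A linear model with a single shared spread per gene was fitted to all 16 libraries with limma 3.58.1 in R 4.3.3 (moderated statistics with a mean-variance trend), and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called changed at an adjusted p under 0.05, and 2-fold counts also required a log2 difference of at least 1. Since 1 FPKM was added, log2 differences understate the change of genes of low expression. The comparisons were bleomycin with vehicle, doxorubicin with vehicle, IL-1β with vehicle, the mean of bleomycin and doxorubicin with IL-1β, and bleomycin with doxorubicin. Other versions used were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

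The groups, comparisons, tests, filter, pseudocount, 29 gene lists, rule for named genes and alternatives were chosen before the data were examined. The lists were written from general knowledge, not from these samples. They covered p53 targets, CDK inhibitors, senescence-associated secretory phenotype (SASP) factors, DNA replication and S phase, mitosis and G2/M, DNA repair, nuclear lamina and chromatin, cartilage matrix and chondrocyte identity, chondrocyte hypertrophy, fibroblast-like matrix and dedifferentiation, and matrix-degrading enzymes. Others covered NF-kB targets, interferon-stimulated genes, NRF2 targets, lysosome, cholesterol synthesis, ATF4 and unfolded protein response, TGF-beta response and mitochondrial transcripts. Marker lists for other cell types covered macrophages, endothelium, osteoblasts, osteoclasts, tendon and ligament, synovial fibroblasts, skeletal muscle, adipocytes, erythroid cells and keratinocytes. Lists with at least 3 tested genes were tested, 26 in number. The list of mitochondrial transcripts had 0 rows, 1 of 11 endothelial markers was tested, and 0 of 7 erythroid markers were tested. Other marker lists were tested in part: 3 of 8 osteoclast, 5 of 15 macrophage, 5 of 9 synovial fibroblast and 6 of 10 osteoblast markers. The tests also held 5 of 6 tendon, 4 of 12 skeletal muscle, 6 of 8 adipocyte and 3 of 6 keratinocyte markers. Counts of list members below are out of the tested members only. Some lists share genes: the NF-kB and SASP lists share 10, the matrix-degrading and SASP lists 8, the osteoblast and hypertrophy lists 3, the osteoclast and matrix-degrading lists 2, the hypertrophy and SASP lists 2, and the synovial fibroblast and cartilage lists 1.

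Lists were tested and, unless fry is named, called with camera (limma). It compares members with all other genes at a preset correlation of 0.01, two-sided and adjusted over the lists of a comparison. It was also run with a correlation estimated per list, and beside it fry, which asks whether members move on balance in 1 direction. The rule named 17 genes in every comparison (Cdkn1a, Cdkn2a, Cdkn2b, Trp53, Mdm2, Lmnb1, Mki67, Gdf15, Il6, Cxcl1, Mmp3, Mmp13, Adamts4, Adamts5, Col2a1, Acan and Sox9). To these it added up to 3 members per list with the largest change among those past the test with no overlap between the libraries of both sides, and the 5 largest increases and 5 largest decreases with a mean of at least 5 FPKM. Fewer could be named than the rule allowed. Overlaps of called genes between treatments share the vehicle libraries, so each was set beside the number expected for independent calls, the mean of 20 simulations with no effect that kept the shared vehicle, and the mean over the 6 assignments in which 2 vehicle libraries served each treatment.

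The model was tested on simulated data with the spread of these libraries, in 10 simulations with 200 changed genes per comparison. In the bleomycin comparison 26.8% of simulated 1.25-fold changes, 66.8% of 1.5-fold changes, 91.2% of 2-fold changes and 97.8% of 4-fold changes were recovered, with 4.2% false calls. The doxorubicin comparison recovered 25.8%, 65.6%, 92.4% and 97.6% of these, with 6.3% false calls. With no simulated change, in the IL-1β comparison, 0 genes were called.

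Alternatives were other pseudocounts (0.1 and 0.01), no filter, a stricter filter (mean of at least 5 FPKM), median-of-ratios scaling, quantile normalization, rescaling of FPKM to a fixed sum (TPM), fits of only the libraries compared, library weights, a replicate block, and leaving out each library in turn. No sample was left out of the main comparisons. The replicate number was not used as a pairing, since nothing in the labels says what it marks. Whether replicates came from different animals, different cultures or repeated wells is not stated, so p-values measure the spread between these libraries.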

Results

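Gene expression was measured by RNA sequencing in primary mouse articular chondrocytes, the cells of joint cartilage, kept at 3% oxygen in medium with 10% fetal bovine serum. There were 4 groups of 4 libraries: vehicle, bleomycin, doxorubicin and IL-1β. Bleomycin, which breaks DNA, was given at 50 µg/mL for 24 h after a 4 h pretreatment with hyaluronidase at 4 U/mL, and the cells then stayed in fresh medium for 5 days. Doxorubicin, a topoisomerase II poison, was given at 50 nM for 5 days with fresh medium every 48 h. IL-1β, an inflammatory cytokine used by the study as an acute stress control, was given at 1 ng/mL for 24 h, and the vehicle named beside it was an equal volume of saline for 24 h. The labels do not state when the vehicle was harvested or whether it received hyaluronidase, so neither equal time in culture nor equal handling of the drug groups and the vehicle is known. Estimated depth was 15.7 to 21.9 M fragments per library. Between 12014 and 12481 genes per library had at least 1 FPKM. In the text below, levels are mean ± SD FPKM of 4 libraries per group, folds are ratios of these means, and log2 differences are on the log2(FPKM + 1) scale with their SE. Coordinates are on GRCm38, and every gene given with coordinates is annotated as protein coding.

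Libraries grouped by treatment. The correlation of log2 values across tested genes was 0.985 to 0.990 between replicates of a group and 0.925 to 0.984 between groups; genes are not independent replicates. The first component held 46.9% of the variance and set IL-1β apart from both drug groups. The second held 24.8% and set the vehicle apart from the other groups.

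**Figure D1:**
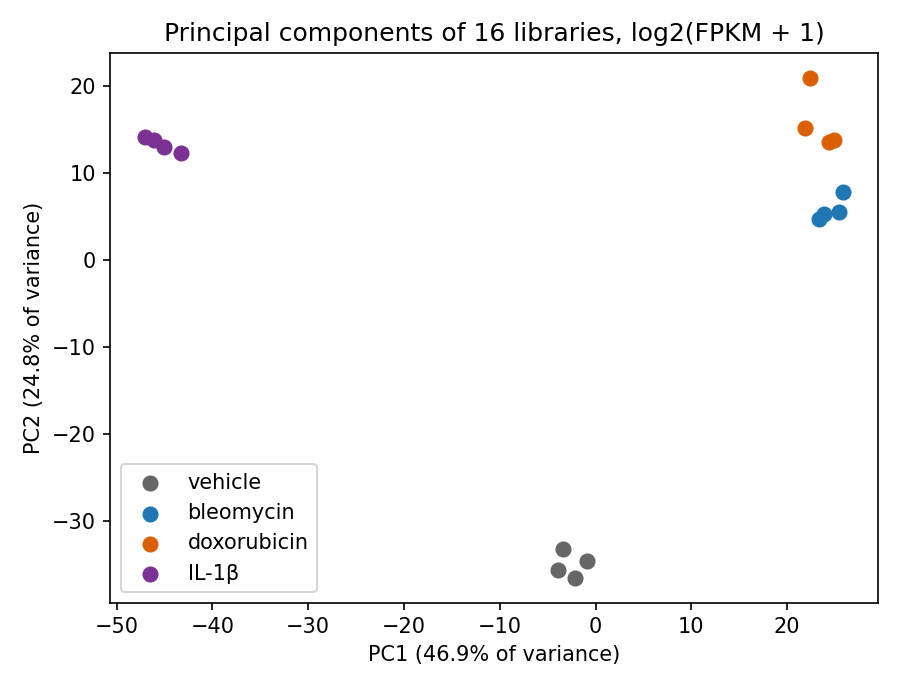
Each point is 1 of the 16 libraries, placed by its scores on PC1 (x axis, 46.9% of the variance) and PC2 (y axis, 24.8%) of log2(FPKM + 1), and colours mark the 4 groups. The 4 libraries of each group lie together, and bleomycin and doxorubicin lie next to each other.

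The first comparison asked which transcripts differed after bleomycin, a treatment the study used to induce senescence, the lasting arrest of damaged cells. Cdkn1a (ENSMUSG00000023067.14, chromosome 17, 29090976 to 29100727), which encodes the cell-cycle inhibitor p21, rose 2.48-fold, from 122 ± 4.55 to 302 ± 11.2 FPKM (log2 difference 1.30 ± 0.05, adjusted p = 2.3e-11). Isg15 (ENSMUSG00000035692.7, chromosome 4, 156199424 to 156200818), a ubiquitin-like protein induced by interferon, rose from 2.12 ± 0.817 to 75.4 ± 20.1 FPKM (log2 difference 4.61 ± 0.21, adjusted p = 1.52e-10). Lmnb1 (ENSMUSG00000024590.8, chromosome 18, 56707813 to 56753424), which encodes lamin B1 of the nuclear lamina, fell 2.75-fold, from 22.7 ± 2.22 to 8.26 ± 0.462 FPKM (log2 difference -1.35 ± 0.09, adjusted p = 5.49e-09). The chemokine gene Cxcl1 (ENSMUSG00000029380.11, chromosome 5, 90891241 to 90893115) fell 4.68-fold, from 38.5 ± 13.5 to 8.23 ± 1.53 FPKM. On the log2(FPKM + 1) scale the largest increase was that of Msmp, from 8.42 ± 2.77 to 289 ± 39.7 FPKM, and the largest decrease after that of the predicted gene Gm49394 was that of Tnmd, a tendon gene that encodes tenomodulin, from 15.9 ± 2.63 to 2.37 ± 0.208 FPKM.

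Lists of cell-cycle, p53, lamina and DNA repair genes were tested 1 by 1 after bleomycin. Of 33 p53 targets, 26 rose, 2 fell and 5 did not pass, with 26 and 2 adjusted over the list alone (camera adjusted p = 1.5e-07, and adjusted p = 0.043 with an estimated correlation). Examples were Ephx1, an epoxide hydrolase, which rose 3.49-fold, Trp53inp1, which rose 3.66-fold, and Mdm2, the ubiquitin ligase that degrades p53, which rose 1.66-fold to 64.7 ± 4.22 FPKM. Trp53 itself fell 1.38-fold, from 52.8 ± 0.523 to 38.1 ± 0.782 FPKM. Of 7 CDK inhibitors, 4 rose and 3 did not pass, with the same counts adjusted over the list alone. Camera did not call the list (adjusted p = 0.092), whereas fry called it up (adjusted p = 5.8e-08). Cdkn2a, the locus of p16 and p19ARF, rose 2.1-fold, from 6.13 ± 0.527 to 12.9 ± 0.924 FPKM, and Cdkn2b, which encodes p15, rose 1.63-fold. Replication genes fell, 31 of 36, while 2 rose and 3 did not pass, with 33 lower and 2 higher adjusted over the list alone (adjusted p = 1.1e-13, and adjusted p = 0.043 with an estimated correlation). Mcm5 of the replicative helicase fell 2.14-fold and Uhrf1, which maintains DNA methylation, fell 2.12-fold. Mitosis genes fell in 31 of 32 cases and in 32 of 32 adjusted over the list alone (adjusted p = 5.1e-18, and adjusted p = 0.043 with an estimated correlation). Birc5, which encodes survivin, fell 2.17-fold, Ube2c fell 2.08-fold, and Mki67, the gene of the Ki-67 proliferation antigen, went from 4.82 ± 1.54 to 2.21 ± 1.44 FPKM, a decrease past the test (adjusted p = 0.00787) although the libraries overlapped. Of 15 genes of nuclear lamina and chromatin, 10 fell and 1 rose, with the same counts adjusted over the list alone (adjusted p = 8.1e-05, and adjusted p = 0.053 with an estimated correlation), among them Tmpo, which fell 2.13-fold. Of 32 DNA repair genes, 17 fell and 1 rose, again with the same counts adjusted over the list alone (adjusted p = 0.00016, and adjusted p = 0.11 with an estimated correlation).

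Interferon-stimulated genes rose in 27 of 28 cases after bleomycin, and in 27 adjusted over the list alone (adjusted p = 2.1e-16, and adjusted p = 0.045 with an estimated correlation). Ifit1 rose from 0.207 ± 0.155 to 12 ± 4.01 FPKM, Usp18 from 0.195 ± 0.16 to 10 ± 2.79 FPKM, and Bst2, which encodes tetherin, from 6.11 ± 0.974 to 71.8 ± 21.2 FPKM. All 30 lysosome genes rose, also adjusted over the list alone (adjusted p = 5.2e-17, and adjusted p = 0.0012 with an estimated correlation). Ctsd (ENSMUSG00000007891.16, chromosome 7, 142375911 to 142388038), which encodes cathepsin D, rose 2.4-fold from 480 ± 24.4 to 1151 ± 57.6 FPKM, and Hexa, a subunit of hexosaminidase, rose 2.44-fold. Cholesterol synthesis genes fell in 19 of 21 cases, while 19 were lower and 1 higher adjusted over the list alone (adjusted p = 1.7e-09, and adjusted p = 0.043 with an estimated correlation). Fdps (ENSMUSG00000059743.12, chromosome 3, 89093588 to 89101959), which encodes farnesyl diphosphate synthase, fell 2.11-fold, from 64.6 ± 7.27 to 30.6 ± 5.06 FPKM. Of 20 genes of the ATF4 and unfolded protein response, 12 fell and 2 rose, with 13 and 3 adjusted over the list alone (adjusted p = 8.4e-06, and adjusted p = 0.045 with an estimated correlation). The amino acid transporter gene Slc7a5 fell 2.6-fold, and Shmt2, of mitochondrial serine metabolism, fell 2.37-fold. Cth, which encodes cystathionine gamma-lyase, fell 3.87-fold.

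Inflammatory and secreted factors split after bleomycin. Of 56 SASP factors, 26 rose, 9 fell and 21 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.019, and adjusted p = 0.35 with an estimated correlation). Plat, which encodes tissue plasminogen activator, rose 4.24-fold, from 6.63 ± 0.685 to 28.1 ± 2.16 FPKM, and Spp1, which encodes osteopontin, rose 3.2-fold. Il6 fell from 2.08 ± 0.928 to 0.364 ± 0.152 FPKM (adjusted p = 0.000102), Cxcl5 fell 4.66-fold, and Ptx3, which encodes pentraxin 3, fell 3.5-fold. Gdf15 was not past the test, at 8.66 ± 1.41 FPKM in vehicle and 10 ± 1.52 FPKM in bleomycin (adjusted p = 0.183). Of 30 NF-kB targets, 11 fell and 4 rose, with the same counts adjusted over the list alone (adjusted p = 0.015, and adjusted p = 0.39 with an estimated correlation). Saa3 (ENSMUSG00000040026.8, chromosome 7, 46711998 to 46715700), an acute-phase gene, fell 3.08-fold, from 156 ± 71.2 to 50.6 ± 15.8 FPKM. Of 18 NRF2 targets, 9 rose and 4 fell, and of 16 TGF-beta response genes 9 rose and 2 fell, the same adjusted over each list alone. Camera called neither list (adjusted p = 0.43 and 0.11), fry both up.

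Cartilage genes moved in both directions after bleomycin: 13 of 24 fell, 5 rose and 6 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.035, and adjusted p = 0.56 with an estimated correlation). Acan (ENSMUSG00000030607.7, chromosome 7, 79053483 to 79115099), which encodes aggrecan, fell 2.05-fold, from 620 ± 74.4 to 303 ± 29.5 FPKM (adjusted p = 4.96e-07). Col2a1 (ENSMUSG00000022483.17, chromosome 15, 97975602 to 98004695), the main collagen of cartilage, fell 1.41-fold, from 8971 ± 1190 to 6356 ± 718 FPKM (adjusted p = 0.000935), and Sox9, the chondrocyte transcription factor, fell 1.29-fold. Cytl1 rose 3.59-fold, and Prg4 (ENSMUSG00000006014.16, chromosome 1, 150449412 to 150466165), which encodes the joint lubricant lubricin, rose 2.63-fold, from 21.1 ± 2.52 to 55.6 ± 4.03 FPKM. Of 10 hypertrophy genes, 6 fell, 1 rose and 3 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.019, and adjusted p = 0.079 with an estimated correlation). Of 19 matrix-degrading enzymes, 14 rose and 3 fell, with the same counts adjusted over the list alone (adjusted p = 0.0043, and adjusted p = 0.13 with an estimated correlation). The aggrecanase gene Adamts5 rose 1.35-fold, Adamts4 rose from 1.67 ± 0.424 to 2.57 ± 0.42 FPKM. The stromelysin gene Mmp3 rose from 16.6 ± 6.53 to 27.8 ± 5.84 FPKM (adjusted p = 0.0178), while collagenase gene Mmp13 stood at 182 ± 52.8 and 196 ± 27.7 FPKM (adjusted p = 0.561). Of 16 fibroblast-like genes, 4 rose, among them Dcn, which rose 2.3-fold, and 4 fell, among them Acta2, which encodes smooth muscle actin and fell 2.5-fold. Adjusted over the list alone the counts were the same, and the list was not called (adjusted p = 0.74). Camera gave it a direction down, its median of 0.04 and mean of 0.02 were above 0, and the median lay below 0 under median-of-ratios scaling (-0.05).

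Markers of other cell types moved with the bleomycin group. All 6 tested adipocyte markers, of 8 in the list, rose, also adjusted over the list alone (adjusted p = 0.00029, and adjusted p = 0.043 with an estimated correlation). Among them was Adipoq (ENSMUSG00000022878.5, chromosome 16, 23146536 to 23158028), which encodes adiponectin and rose from 0.104 ± 0.125 to 4.06 ± 1.08 FPKM. Adipoq, Cfd and Plin1 of this list stayed under 1 FPKM in every vehicle and IL-1β library. They passed the filter only through the drug groups, which partly set their direction in advance. Of 5 synovial fibroblast markers, 4 rose, also adjusted over the list alone (adjusted p = 0.0049, and adjusted p = 0.043 with an estimated correlation). All 3 tested osteoclast markers, of 8 in the list, rose, also adjusted over the list alone (adjusted p = 0.044, and adjusted p = 0.1 with an estimated correlation). That call ended without vehicle replicate 1 (median 0.36) or bleomycin replicate 3 (median 0.36). Macrophage markers were split, with 3 of 5 higher, among them Cd68, which rose 3.2-fold, and 1 lower. Osteoblast markers had 2 higher and 2 lower of 6, tendon markers 1 higher and 2 lower of 5, keratinocyte markers 1 higher of 3, and skeletal muscle markers 1 lower of 4. Adjusted over each list alone the counts held. Camera called none of these 5 (adjusted p = 0.54, 0.74, 0.18, 0.28 and 0.67), fry macrophage, tendon and keratinocyte markers. Median and mean were -0.15 and 0.34 for osteoblast and 0.03 and -0.06 for muscle markers.

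In all, 6086 of 12976 genes changed with bleomycin, 3619 higher and 2467 lower, and 450 changed at least 2-fold, 341 higher and 109 lower. Camera called 17 of 26 lists, 9 of them also with an estimated correlation, and fry called 22. The share of changed genes that were higher, 59.5%, was 47.7% with median-of-ratios scaling and 48.3% with quantile normalization, and the 2-fold count was 1019 with a pseudocount of 0.01. The call of Mmp3 ended without a filter, without vehicle replicate 2 (log2 difference 0.56) or without bleomycin replicate 4 (0.64), those of Adamts4 and Col2a1 (log2 difference 0) with quantile normalization, and that of the cartilage list under several settings, among them without bleomycin replicate 1 (median -0.24) or vehicle replicate 3 (-0.25). The calls of the hypertrophy and osteoclast lists ended with a stricter filter, where the medians were -0.57 and 0.69 against -0.47 and 0.38. Calls were gained for Gdf15 without vehicle replicate 1 (log2 difference 0.28), for the CDK inhibitor and TGF-beta lists without a filter or with quantile normalization, and for the keratinocyte list without a filter.

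Doxorubicin, the other drug the study used to induce senescence, was compared with vehicle in the same way. Cdkn1a rose 2.69-fold, to 327 ± 17.9 FPKM (log2 difference 1.42 ± 0.05, adjusted p = 9.92e-12). On the log2(FPKM + 1) scale Lmnb1 showed the largest decrease after that of the predicted gene Gm49394, falling 5.81-fold to 3.91 ± 0.498 FPKM (log2 difference -2.27 ± 0.09, adjusted p = 1.99e-11). Isg15 showed the largest increase on that scale, to 96.8 ± 6.32 FPKM (log2 difference 5.01 ± 0.21, adjusted p = 4.23e-11). Mmp3 (ENSMUSG00000043613.8, chromosome 9, 7445822 to 7455975) rose 10-fold, from 16.6 ± 6.53 to 166 ± 68.1 FPKM (log2 difference 3.25 ± 0.25, adjusted p = 2.58e-08), and Saa3 rose 9.91-fold to 1543 ± 790 FPKM.

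Cell-cycle genes fell after doxorubicin. All 32 mitosis genes fell, also adjusted over the list alone (adjusted p = 2.5e-22, and adjusted p = 0.023 with an estimated correlation). Among them were Ccna2 (ENSMUSG00000027715.9, chromosome 3, 36564865 to 36572150), which encodes cyclin A2 and fell 4.36-fold to 7.41 ± 0.677 FPKM, Birc5, which fell 4.23-fold, and the spindle checkpoint gene Bub1b, which fell 4.45-fold. Mki67 fell 3.29-fold, to 1.47 ± 0.272 FPKM (adjusted p = 0.00108). Replication genes fell in 33 of 36 cases, and in 34 adjusted over the list alone (adjusted p = 3.5e-19, and adjusted p = 0.019 with an estimated correlation), with Mcm5 down 3.3-fold and Uhrf1 down 3.33-fold. Of 15 lamina and chromatin genes 11 fell, also adjusted over the list alone (adjusted p = 1.8e-06, and adjusted p = 0.024 with an estimated correlation), and Hmgb2, a chromatin protein, fell 3.72-fold. DNA repair genes fell in 20 of 32 cases and 2 rose, with 21 and 2 adjusted over the list alone (adjusted p = 6.7e-06, and adjusted p = 0.055 with an estimated correlation). Of 33 p53 targets, 22 rose and 2 fell, with the same counts adjusted over the list alone (adjusted p = 1.4e-08, and adjusted p = 0.019 with an estimated correlation). Ephx1 rose 4.06-fold, Dcxr, which encodes xylulose reductase, 3.76-fold and Mdm2 1.9-fold, while Trp53 fell to 42.1 ± 2.5 FPKM. Of 7 CDK inhibitors, 2 rose and 1 fell, with the same counts adjusted over the list alone. Camera did not call the list (adjusted p = 0.71), whereas fry called it up (adjusted p = 2.8e-05). Cdkn2b rose 1.46-fold, and Cdkn2a stood at 6.13 ± 0.527 FPKM in vehicle and 6.36 ± 1.02 FPKM in doxorubicin (adjusted p = 0.776).

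All 28 tested interferon-stimulated genes rose with doxorubicin, also adjusted over the list alone (adjusted p = 1.6e-19, and adjusted p = 0.024 with an estimated correlation), with Ifit1 at 17.7 ± 3.58 and Usp18 at 14.2 ± 2.72 FPKM. As stated for bleomycin, Ifit1 and Usp18 passed the filter only through the drug groups. Lysosome genes rose in 29 of 30 cases, also adjusted over the list alone (adjusted p = 1.1e-15, and adjusted p = 0.002 with an estimated correlation), with Ctsd up 2.54-fold and Npc2, a lysosomal cholesterol carrier, up 2.53-fold. Cholesterol synthesis genes fell in 18 of 21 cases, also adjusted over the list alone (adjusted p = 1.2e-08, and adjusted p = 0.024 with an estimated correlation), with Fdps down 2.44-fold. Of 20 ATF4 and unfolded protein response genes, 17 fell and 1 rose, with the same counts adjusted over the list alone (adjusted p = 2.4e-08, and adjusted p = 0.019 with an estimated correlation), with Slc7a5 down 2.92-fold and Shmt2 down 2.76-fold. SASP factors rose in 39 of 56 cases, 1 fell and 16 did not pass, with the same counts adjusted over the list alone (adjusted p = 4.3e-10, and adjusted p = 0.024 with an estimated correlation). Complement C3 rose 6.68-fold to 44 ± 9.75 FPKM, Ccl5 rose from 0.444 ± 0.3 to 5.94 ± 1.16 FPKM, and Spp1 rose 3.9-fold. Il6 stood at 2.08 ± 0.928 and 2.06 ± 0.811 FPKM (adjusted p = 0.994), Cxcl1 at 38.5 ± 13.5 and 39.5 ± 14.9 FPKM (adjusted p = 0.904), and Gdf15 at 8.66 ± 1.41 and 8.39 ± 0.709 FPKM (adjusted p = 0.843). Of 30 NF-kB targets, 13 rose and 3 fell, with 14 and 3 adjusted over the list alone (adjusted p = 0.019, and adjusted p = 0.39 with an estimated correlation), and complement factor Cfb rose 7.6-fold. That call ended without vehicle replicate 2 (median 0.17) or doxorubicin replicate 4 (median 0.15). TGF-beta response genes rose in 10 of 16 cases and 2 fell, with the same counts adjusted over the list alone (adjusted p = 0.019, and adjusted p = 0.055 with an estimated correlation). The NRF2 list, with 9 of 18 higher and 4 lower, the same adjusted over the list alone, was not called (adjusted p = 0.32).

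Acan fell 1.98-fold after doxorubicin to 312 ± 41.1 FPKM, Col2a1 fell 1.38-fold to 6495 ± 764 FPKM and Sox9 fell 1.22-fold, while Prg4 rose 4.61-fold to 97.4 ± 8.72 FPKM and Cytl1 rose 2.68-fold. In the cartilage list 9 of 24 fell, 6 rose and 9 did not pass, with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.4); camera gave the direction down and fry up. Hypertrophy genes fell in 6 of 10 cases and 2 rose, with the same counts adjusted over the list alone (adjusted p = 0.035, and adjusted p = 0.085 with an estimated correlation), and Panx3, a channel gene of maturing chondrocytes, fell 2.35-fold. The hypertrophy call ended with a stricter filter, with median-of-ratios scaling and with replicate number as a block, where the medians were -0.82, -0.74 and -0.70 against -0.70 in the test reported. Of 19 matrix-degrading enzymes, 10 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.00014, and adjusted p = 0.055 with an estimated correlation). Adamts5 rose 2.05-fold, Mmp13 rose 1.93-fold, and Hyal1, a hyaluronidase, rose from 1.16 ± 0.0966 to 6.61 ± 1.63 FPKM, whereas Adamts4 stood at 1.67 ± 0.424 and 2.21 ± 0.223 FPKM (adjusted p = 0.0798). Adamts4 was called with replicate number as a block (log2 difference 0.28) and without vehicle replicate 4 (0.35). Fibroblast-like genes had 7 of 16 higher and 2 lower, the same adjusted over the list alone, and the list was not called (adjusted p = 0.093); Dcn rose 2.88-fold and the proteoglycan gene Lum 2.51-fold.

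Markers of other cell types moved here too. All 6 adipocyte markers rose, also adjusted over the list alone (adjusted p = 4.3e-06, and adjusted p = 0.016 with an estimated correlation). Adipoq reached 13.9 ± 2.98 FPKM, Fabp4, which encodes a fatty acid binding protein, rose 4.5-fold to 141 ± 17.5 FPKM, and Cfd, which encodes adipsin, was listed at 0 in 3 vehicle libraries and reached 8.34 ± 0.927 FPKM. As stated for bleomycin, Adipoq, Cfd and Plin1 passed the filter only through the drug groups. All 5 synovial fibroblast markers rose, also adjusted over the list alone (adjusted p = 7.7e-05, and adjusted p = 0.016 with an estimated correlation), with Cd55 up 4.75-fold. Of 3 osteoclast markers 2 rose, also adjusted over the list alone (adjusted p = 0.025, and adjusted p = 0.055 with an estimated correlation). Macrophage markers had 3 of 5 higher and 1 lower, among them Lyz2, which encodes lysozyme and rose 3.27-fold, tendon markers 3 of 5 lower, osteoblast markers 2 of 6 higher and 3 lower, keratinocyte markers 1 of 3 higher and skeletal muscle markers 1 of 4 lower. Adjusted over each list alone the counts held. Camera called none of these 5 (adjusted p = 0.23, 0.1, 0.69, 0.32 and 0.92), fry macrophage, tendon and keratinocyte markers. Median and mean were -0.24 and 0.20 for osteoblast and 0.13 and -0.02 for muscle markers.

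With doxorubicin 6262 genes changed, 3302 higher and 2960 lower, and 718 changed at least 2-fold, 475 higher and 243 lower. The share of changed genes that were higher, 52.7%, was 47.7% with median-of-ratios scaling, 47.2% with quantile normalization and 48.6% with a stricter filter. Camera called 17 of 26 lists, 11 of them also with an estimated correlation, and fry called 23. The 2-fold count was 1343 with a pseudocount of 0.01 and 456 when genes below a mean of 5 FPKM were left out. The fibroblast-like list was called without a filter and with quantile normalization.

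**Figure D2:**
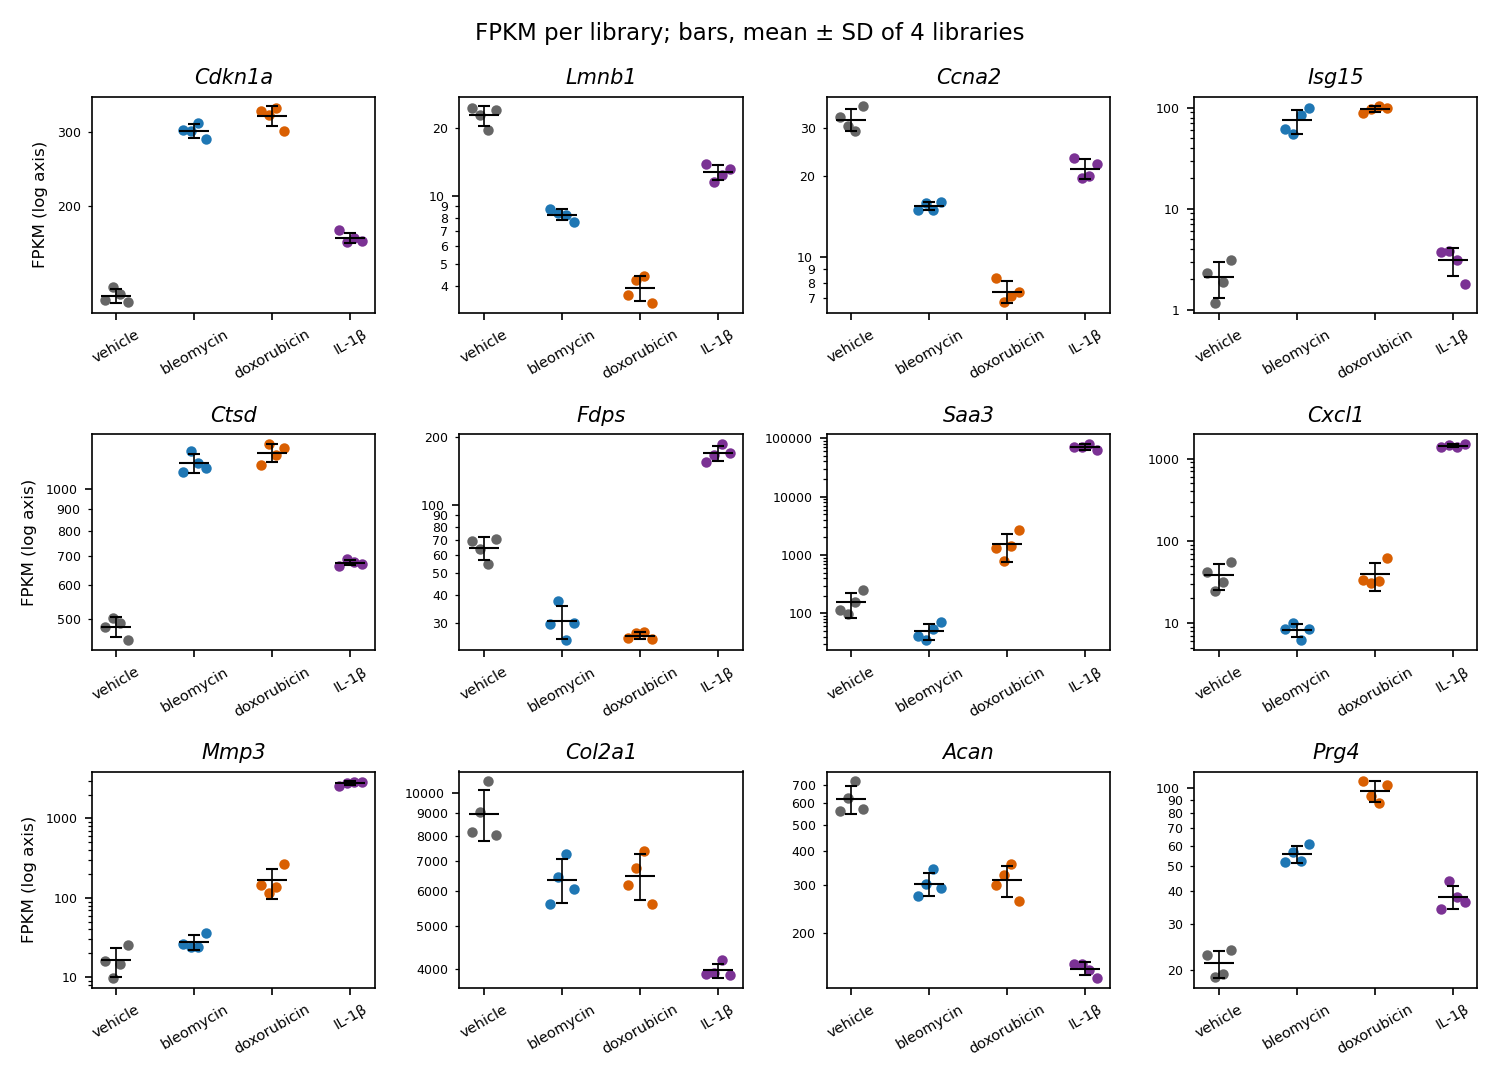
Each panel plots the FPKM of 1 gene on a log axis in 16 libraries (points) with the mean ± SD of the 4 libraries of each group (bars). Cdkn1a, Isg15 and Ctsd stand higher and Lmnb1, Ccna2 and Fdps lower in both drug groups than in vehicle, whereas Saa3, Cxcl1 and Mmp3 stand highest in IL-1β.

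Both drugs were compared for shared changes. The same direction was found for 4828 genes, 2732 higher and 2096 lower in both, and the opposite direction for 33. Independent calls would share 921 higher and 563 lower genes, and with different vehicle libraries for each drug 3619 genes were shared. The covariance of the log2 differences across genes was 0.1991, against 0.009 simulated without an effect and 0.1891 with split vehicle libraries. Of the 2732 genes higher with both drugs, 1750 were also higher in the drug groups than in IL-1β, 1247 were also raised by IL-1β and 312 were lowered by it. Of the 2096 genes lower with both drugs, 1494 were also lower than in IL-1β, 793 were also lowered by IL-1β and 291 were raised by it. These parts depended on scaling: with FPKM rescaled to a fixed sum, of 2772 genes higher with both drugs 2358 were higher than in IL-1β, 636 were raised by IL-1β and 1014 lowered by it. Of 2003 genes lower with both, 686 were lower than in IL-1β, 1564 were lowered by IL-1β and 97 raised by it. With median-of-ratios scaling and quantile normalization 1026 and 938 of the genes higher with both were also raised by IL-1β, and 1120 and 1136 of those lower with both were also lowered by it.

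IL-1β, the acute inflammatory stimulus, was compared with vehicle to set an inflammatory response beside the drug responses. Saa3 rose from 156 ± 71.2 to 70950 ± 7310 FPKM (log2 difference 8.92 ± 0.33, adjusted p = 4.76e-12) and made up as much as 14.4% of all FPKM in a library. Mmp3 rose 169-fold to 2799 ± 138 FPKM (log2 difference 7.39 ± 0.25, adjusted p = 1.93e-12), Cxcl1 rose 37.4-fold to 1438 ± 63.7 FPKM, and Il6 (ENSMUSG00000025746.11, chromosome 5, 30013114 to 30019981) rose 22.8-fold to 47.3 ± 3 FPKM (adjusted p = 5.37e-11). Acan fell 4.19-fold to 148 ± 8.11 FPKM (log2 difference -2.06 ± 0.10, adjusted p = 9.71e-11), and Col2a1 fell 2.26-fold to 3972 ± 147 FPKM. Nos2, the inducible nitric oxide synthase, rose from 0.287 ± 0.323 to 144 ± 19.6 FPKM.

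Of 30 NF-kB targets 28 rose, 29 adjusted over the list alone (adjusted p = 3.9e-21, and adjusted p = 0.012 with an estimated correlation), among them Lcn2, which encodes lipocalin 2 and rose 57.9-fold. SASP factors rose in 41 of 56 cases and fell in 9, with 42 and 9 adjusted over the list alone (adjusted p = 1.1e-10, and adjusted p = 0.033 with an estimated correlation), with the chemokine Ccl2 up 32.8-fold to 1615 ± 94.9 FPKM. Igfbp5, a member of that list, fell 9.39-fold, from 216 ± 19.3 to 23 ± 2.08 FPKM, and Gdf15 fell 1.43-fold. Saa1 and Saa2 reached 200.2 ± 36.6 and 205 ± 34 FPKM; they are paralogs that can share reads, so their separate levels are uncertain. Hp, which encodes haptoglobin, rose from 8.73 ± 3.88 to 1107 ± 134 FPKM. All but 1 of 18 NRF2 targets rose, also adjusted over the list alone (adjusted p = 5.9e-12, and adjusted p = 0.0094 with an estimated correlation), with Gsta4 up 8.08-fold, the ferritin gene Fth1 up 6.25-fold and Hmox1, which encodes heme oxygenase 1, up 3.29-fold. All 21 cholesterol synthesis genes rose, also adjusted over the list alone (adjusted p = 9.6e-16, and adjusted p = 0.0094 with an estimated correlation), with Msmo1 up 3.48-fold and Hsd17b7 up 3.59-fold. Lysosome genes rose in 29 of 30 cases, also adjusted over the list alone (adjusted p = 9.6e-16, and adjusted p = 0.0019 with an estimated correlation), with Npc2 up 2.46-fold and the sialidase gene Neu1 up 2.36-fold. Matrix-degrading enzymes had 8 of 19 higher and 4 lower, with 9 and 5 adjusted over the list alone (adjusted p = 0.034, and adjusted p = 0.28 with an estimated correlation), a call that ended without vehicle replicate 1 (median 0.31). Mmp13 rose 8.37-fold, Mmp10 rose from 0.225 ± 0.0634 to 4.21 ± 0.357 FPKM, Adamts5 rose 1.53-fold, and Adamts4 stood at 1.67 ± 0.424 and 2 ± 0.379 FPKM (adjusted p = 0.285).

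Cartilage genes fell in 19 of 24 cases with IL-1β and 1 rose, with the same counts adjusted over the list alone (adjusted p = 3e-12, and adjusted p = 0.085 with an estimated correlation). Matn1, which encodes a cartilage matrilin, fell 8.88-fold from 433 ± 140 to 48.7 ± 4.8 FPKM, Matn3 fell 5.38-fold and Sox9 fell 1.84-fold. Fibroblast-like genes fell in 12 of 16 cases and 4 rose, with the same counts adjusted over the list alone (adjusted p = 6.4e-05, and adjusted p = 0.083 with an estimated correlation), with Col1a2 down 3.17-fold and Col3a1 down 2.98-fold. Hypertrophy genes had 3 of 10 higher and 5 lower, the same adjusted over the list alone, and the list was not called (adjusted p = 0.66); its median was -0.29, its mean 0.12, and fry gave the direction up (adjusted p = 0.039). TGF-beta response genes had 7 of 16 higher and 7 lower, with 8 and 7 adjusted over the list alone, and were not called as a list (adjusted p = 0.7), with a median of 0.34 and a mean of -0.06. Ccn2, which encodes connective tissue growth factor, fell 3.3-fold and Tgfbi fell 2.68-fold. ATF4 and unfolded protein response genes fell in 13 of 20 cases and 3 rose, with the same counts adjusted over the list alone (adjusted p = 7.3e-05, and adjusted p = 0.083 with an estimated correlation), with Slc7a5 down 2.39-fold and Chac1 down 2.17-fold. Other large decreases were those of C1qtnf3, 7.98-fold, Fgf21, 10.3-fold, and Arsi, 6.03-fold.

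Cell-cycle and p53 lists were tested with IL-1β as well. Mitosis genes fell in 22 of 32 cases, also adjusted over the list alone (adjusted p = 1.9e-05, and adjusted p = 0.28 with an estimated correlation). Foxm1 fell 2-fold, Anln fell 1.63-fold and Ccna2 fell 1.52-fold, while Mki67 stood at 4.82 ± 1.54 and 5.82 ± 1.26 FPKM (adjusted p = 0.463). Replication genes fell in 11 of 36 cases and 2 rose, Tyms 1.71-fold and Chaf1b 1.42-fold, with the same counts adjusted over the list alone (adjusted p = 0.02, and adjusted p = 0.44 with an estimated correlation). DNA repair genes fell in 12 of 32 cases and 2 rose, the same adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.28 with an estimated correlation). Of 15 lamina and chromatin genes 6 fell and 1 rose, the same adjusted over the list alone (adjusted p = 0.048, and adjusted p = 0.29 with an estimated correlation), and Lmnb1 fell 1.79-fold. That list call ended without vehicle replicates 1 or 2 or IL-1β replicate 1 (medians -0.05, -0.07 and -0.08), with a pseudocount of 0.01 (-0.07) and with replicate number as a block (-0.07). Of 33 p53 targets 18 rose and 3 fell, with 21 and 3 adjusted over the list alone (adjusted p = 0.00035, and adjusted p = 0.094 with an estimated correlation), among them the death receptor gene Fas, up 4.19-fold. Cdkn1a rose 1.37-fold to 167 ± 4.92 FPKM, Mdm2 1.32-fold, Trp53 1.14-fold, Cdkn2a 1.57-fold and Cdkn2b 1.97-fold, and Cdkn1c, which encodes p57, fell 2.05-fold. The CDK inhibitor list, with 4 of 7 higher and 1 lower in the count adjusted over the list alone as well, was not called (adjusted p = 0.23). Interferon-stimulated genes rose in 8 of 28 cases, 7 adjusted over the list alone (adjusted p = 0.049, and adjusted p = 0.61 with an estimated correlation), among them Gbp2, up 5.59-fold, and Cxcl10, from 0.156 ± 0.1 to 4.81 ± 1.04 FPKM. This call ended without vehicle replicates 1, 2 or 3 or IL-1β replicates 1, 2 or 4 (medians 0.15 to 0.21), and Isg15 stood at 2.12 ± 0.817 and 3.11 ± 0.935 FPKM (adjusted p = 0.136).

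Markers of other cell types included all 3 tested osteoclast markers, of 8 in the list, which rose, also adjusted over the list alone (adjusted p = 0.0053, and adjusted p = 0.041 with an estimated correlation). Of 6 adipocyte markers 3 rose, also adjusted over the list alone (adjusted p = 0.049, and adjusted p = 0.22 with an estimated correlation). Fabp4 rose 11.7-fold and Lpl 3.71-fold, and this call ended without vehicle replicate 1 or IL-1β replicate 4 (medians 0.39 and 0.39), with smaller pseudocounts (0.35 and 0.13) and with a fit of the compared libraries alone (0.37). Tendon markers fell in 3 of 5 cases, also adjusted over the list alone (adjusted p = 0.036, and adjusted p = 0.22 with an estimated correlation), a call that ended without IL-1β replicate 1 (median -0.37). Macrophage markers had 3 of 5 higher, among them Cd68, up 5.62-fold, and Cd14, up 4.11-fold, and 2 lower, whereas the pan-leukocyte gene Ptprc stayed at 0.00768 ± 0.00513 FPKM. Osteoblast markers had 2 of 6 higher and 3 lower, synovial fibroblast markers 1 of 5 higher and 1 lower, skeletal muscle markers 3 of 4 lower, and keratinocyte markers 1 of 3 higher and 1 lower. Adjusted over each list alone the counts held. Camera called neither the macrophage list nor these 4 (adjusted p = 0.23, 0.76, 0.98, 0.066 and 0.98), fry macrophage and muscle markers. The osteoblast list had a median of -0.21 and mean of 0.43, the synovial fibroblast and keratinocyte lists medians of 0.01 and 0.15 with camera direction down.

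With IL-1β 5574 genes changed, 3181 higher and 2393 lower, and 731 changed at least 2-fold, 503 higher and 228 lower. The share of changed genes that were higher, 57.1%, was 48.5% with median-of-ratios scaling and 44% with quantile normalization. Camera called 18 of 26 lists, 6 of them also with an estimated correlation, and fry called 23. Rescaling FPKM to a fixed sum moved the median log2 difference of all genes by -0.34, so that Trp53 (-0.18), Mki67 (-0.06), Adamts4 (-0.07) and the medians of the CDK inhibitor (-0.11) and synovial fibroblast (-0.31) lists lay below 0, and 8133 genes were then called, 16.1% of them higher. Under it, p53 targets had 8 members higher and 8 lower, lysosome genes 21 and 2, matrix-degrading enzymes 7 and 7, NRF2 targets 14 and 0, cholesterol synthesis genes 19 and 0 and NF-kB targets 27 and 0. The calls of Cdkn1a (0.09), Mdm2 (0.02), Chaf1b (0.13) and the tendon list (median -0.84) then ended, and the macrophage list was called. Trp53 (0.07) and the tendon list (-0.52) lost their calls with quantile normalization, and the matrix-degrading list (0.38) with a pseudocount of 0.01. With a stricter filter the macrophage list was called and the calls of 7 lists ended: replication (median -0.095), DNA repair (-0.155), interferon (0.15), lamina (-0.07), matrix-degrading (0.15), osteoclast (0.71) and tendon (-0.71). The skeletal muscle list was called without a filter and without IL-1β replicate 2 (median -0.69).

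**Figure D3:**
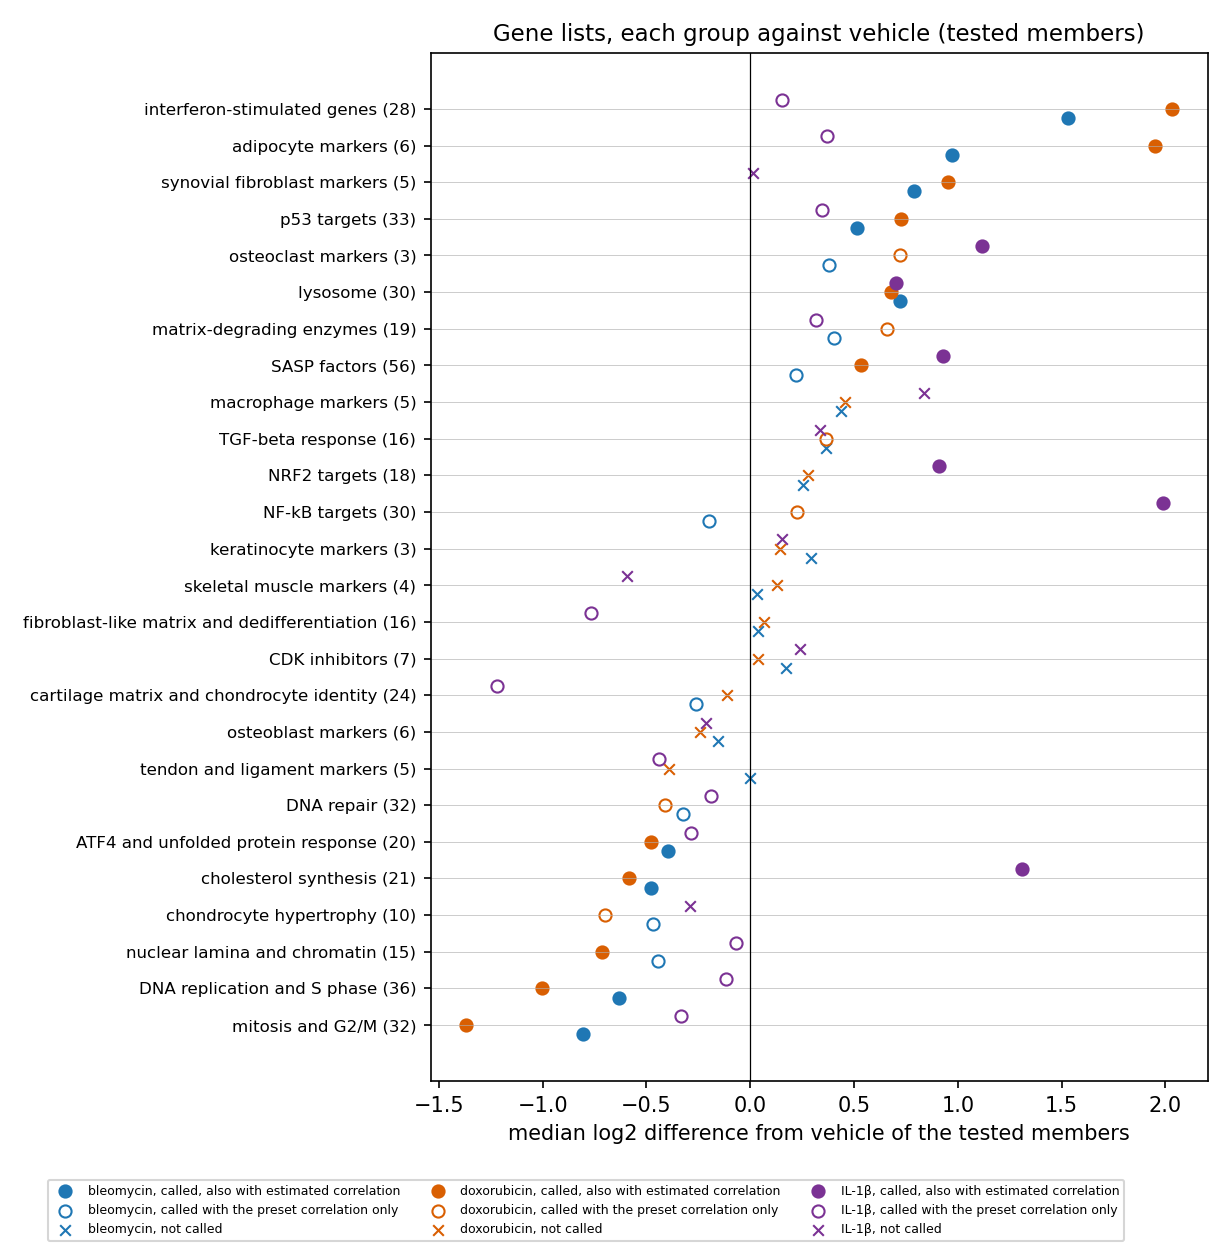
Each mark is the median log2 difference from vehicle, on the log2(FPKM + 1) scale, of the tested members of a list (number in brackets) in bleomycin, doxorubicin or IL-1β. Filled marks were called by camera with the preset and the estimated correlation, open marks with the preset correlation only, and crosses were not called; cholesterol synthesis genes lay below 0 in both drug groups and above 0 in IL-1β.

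Overlaps with IL-1β were smaller than that between the drugs. Bleomycin and IL-1β changed 2406 genes in the same direction, 1494 higher and 912 lower, and 783 in opposite directions. Independent calls would share 887 and 455, and split vehicle libraries gave 1710. The covariance was 0.0621, against 0.0089 simulated and 0.052 with split vehicle libraries. Doxorubicin and IL-1β changed 2502 genes in the same direction, 1488 higher and 1014 lower, and 838 in opposite directions. Independent calls would share 809 and 546, and split vehicle libraries gave 1825, with a covariance of 0.0972 against 0.0089 simulated and 0.0871 split. The directions of these overlaps depended on scaling: with FPKM rescaled to a fixed sum, bleomycin and IL-1β shared 710 higher and 1794 lower genes, and doxorubicin and IL-1β shared 777 and 2152. Lower genes also outnumbered higher ones with median-of-ratios scaling (1315 and 1157 for bleomycin, 1321 and 1301 for doxorubicin) and with quantile normalization (1332 and 1074, 1372 and 1175).

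The mean of both drug groups was then tested directly against IL-1β, which asks how the drug states differed from the inflammatory one. Saa3 was lower in the drug groups (log2 difference -8.06 ± 0.28, adjusted p = 1.15e-12), at 50.6 ± 15.8 FPKM in bleomycin and 1543 ± 790 in doxorubicin against 70950 ± 7310 in IL-1β. Folds in this comparison set the mean over both drug groups against IL-1β, and the drug groups also differed from each other for several of the genes named, among them Cxcl1, Mmp3, Il6 and Ccl2. Cxcl1 was 60.3-fold lower, Mmp3 28.8-fold lower and Il6 39.1-fold lower. Isg15 was 27.7-fold higher (log2 difference 4.41 ± 0.18, adjusted p = 6.5e-12). Msmp was higher by 6.84 ± 0.16 on the log2 scale, with 0.658 ± 0.308 FPKM in IL-1β. Penk, which encodes proenkephalin, was 16.9-fold higher and Dkk3, a secreted member of the dickkopf family, 15.1-fold higher.

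NF-kB targets were lower in the drug groups in 27 of 30 cases and higher in 1, with the same counts adjusted over the list alone (adjusted p = 7.2e-16, and adjusted p = 0.033 with an estimated correlation), with Ccl2 32.8-fold lower. All 21 cholesterol synthesis genes were lower, also adjusted over the list alone (adjusted p = 3e-17, and adjusted p = 0.018 with an estimated correlation), with Fdps 5.92-fold and Msmo1 5.46-fold lower. NRF2 targets were lower in 16 of 18 cases, also adjusted over the list alone (adjusted p = 1.3e-08, and adjusted p = 0.033 with an estimated correlation), with Fth1 4.01-fold lower and Gsr, which encodes glutathione reductase, 3.67-fold lower. Interferon-stimulated genes were higher in 25 of 28 cases and lower in 2, with 26 and 2 adjusted over the list alone (adjusted p = 3.8e-12, and adjusted p = 0.12 with an estimated correlation). Ifit1 and Usp18 stood at 0.335 ± 0.0692 and 0.316 ± 0.123 FPKM in IL-1β. Mitosis genes were lower in 31 of 32 cases, 32 adjusted over the list alone (adjusted p = 8.2e-12, and adjusted p = 0.12 with an estimated correlation), with Cenpa 2.51-fold and Mki67 3.17-fold lower. Replication genes were lower in 32 of 36 cases and higher in 1, the same adjusted over the list alone (adjusted p = 5.8e-10, and adjusted p = 0.12 with an estimated correlation), with Tyms 3.08-fold and Chaf1b 2.73-fold lower. Lamina and chromatin genes were lower in 10 of 15 cases and higher in 1, the same adjusted over the list alone (adjusted p = 0.0059, and adjusted p = 0.2 with an estimated correlation), with Hmgb2 3.07-fold and Lmnb1 2.09-fold lower. Of 33 p53 targets 21 were higher and 4 lower, with 21 and 5 adjusted over the list alone (adjusted p = 0.0065, and adjusted p = 0.21 with an estimated correlation), with Ephx1 3.26-fold, Cdkn1a 1.88-fold and Mdm2 1.34-fold higher, whereas Trp53 was 1.51-fold lower.

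Cartilage genes were higher in the drug groups than in IL-1β in 19 of 24 cases, also adjusted over the list alone (adjusted p = 1.5e-09, and adjusted p = 0.15 with an estimated correlation). Cytl1 was 14.9-fold, Matn1 9.14-fold, Comp, which encodes cartilage oligomeric matrix protein, 4.17-fold, Acan 2.08-fold, Col2a1 1.62-fold and Sox9 1.46-fold higher. Fibroblast-like genes were higher in 13 of 16 cases and lower in 3, the same adjusted over the list alone (adjusted p = 5e-05, and adjusted p = 0.12 with an estimated correlation), with Col3a1 4.85-fold and Lum 3.4-fold higher. Synovial fibroblast markers were higher in 5 of 5 cases, also adjusted over the list alone (adjusted p = 0.00041, and adjusted p = 0.033 with an estimated correlation). SASP factors were lower in 29 of 56 cases and higher in 21, the same adjusted over the list alone (adjusted p = 0.035, and adjusted p = 0.42 with an estimated correlation), and Gdf15 was 1.52-fold higher. Lysosome genes were split, 13 of 30 higher, among them Ctsd 1.75-fold and Laptm4a 1.51-fold, and 11 lower, with 13 and 13 adjusted over the list alone; the list was not called (adjusted p = 0.63), its median was -0.09 and its mean 0.03. Matrix-degrading enzymes, with 8 of 19 higher and 6 lower in the count adjusted over the list alone too, were not called (adjusted p = 0.6), with a median of 0.13 and a mean of -0.29. Mmp13 was 5.55-fold lower, Cdkn2b was 1.27-fold lower, and Cdkn2a (difference -0.08 ± 0.08), Adamts4 (0.18 ± 0.11) and Adamts5 (0.11 ± 0.07) did not pass. The drug groups lay on opposite sides of IL-1β for Cdkn2a, at 12.9 ± 0.924 in bleomycin and 6.36 ± 1.02 in doxorubicin against 9.62 ± 0.585 FPKM, and for Adamts5, at 14.4 ± 1.32 and 21.8 ± 2.27 against 16.3 ± 1.08 FPKM. DNA repair genes were lower in 14 of 32 and higher in 2, ATF4 and unfolded protein response genes lower in 13 of 20 and higher in 4, and hypertrophy genes lower in 6 of 10 and higher in 4, the same adjusted over each list alone. Camera called none of these 3 (adjusted p = 0.076, 0.076 and 0.32), fry all down. The CDK inhibitor list was not called (adjusted p = 0.91) and had a median of -0.08 and a mean of 0.12.

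In this comparison 7529 genes differed, 3702 higher and 3827 lower in the drug groups, and 880 differed at least 2-fold, 444 higher and 436 lower. The share of higher genes, 49.2%, was 51.9% with quantile normalization and 50.3% without a filter. Camera called 12 of 26 lists, 4 of them also with an estimated correlation, and fry called 24. Rescaling to a fixed sum moved the median of all genes by 0.346 and gave 83.7% of called genes as higher, and Cdkn2a (0.28) and Cdkn2b (0.03) then lay above IL-1β. Under it, Adamts4 (0.52), Adamts5 (0.48) and the lysosome list (median 0.29) gained calls as higher. In that setting, lysosome genes were higher in 25 cases and lower in 1, DNA repair genes in 13 and 5, ATF4 and unfolded protein response genes in 9 and 4, and lamina and chromatin genes in 5 and 5. The call of the SASP list ended with smaller pseudocounts, a stricter filter, quantile normalization and a replicate block (medians -0.18 to -0.48). Calls were gained for the DNA repair list without a filter, with quantile normalization and without IL-1β replicate 3 (median -0.24), and for the ATF4 and unfolded protein response list without a filter and without IL-1β replicate 2 (-0.29).

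Bleomycin and doxorubicin were last compared with each other, and the groups differed in dose, exposure and recovery time. Only the bleomycin group is listed with the hyaluronidase pretreatment, and only the doxorubicin group with fresh medium every 48 h. These differences cannot be told apart from the drugs. Saa3 was 30.5-fold lower in bleomycin, at 50.6 ± 15.8 against 1543 ± 790 FPKM (log2 difference -4.82 ± 0.33, adjusted p = 3.8e-07). C3 was 8.05-fold lower, Lcn2 12.5-fold lower at 27.2 ± 3.89 against 340 ± 162 FPKM, Mmp3 5.97-fold lower, Cxcl1 4.8-fold lower and Il6 5.65-fold lower. Lmnb1 was 2.11-fold higher in bleomycin and Ccna2 2.08-fold higher, at 15.4 ± 0.564 against 7.41 ± 0.677 FPKM. Cdkn2a was 2.02-fold higher in bleomycin, at 12.9 ± 0.924 against 6.36 ± 1.02 FPKM (log2 difference 0.92 ± 0.09, adjusted p = 1.57e-05), while Cdkn1a stood at 302 ± 11.2 and 327 ± 17.9 FPKM (adjusted p = 0.157).

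Mitosis genes were higher in bleomycin than in doxorubicin in 26 of 32 cases, 29 adjusted over the list alone (adjusted p = 4e-22, and adjusted p = 0.021 with an estimated correlation), with Birc5 1.95-fold higher. Replication genes were higher in 22 of 36 cases, 31 adjusted over the list alone (adjusted p = 2.6e-17, and adjusted p = 0.021 with an estimated correlation), with Ccne2, which encodes cyclin E2, 1.87-fold and Mcm6 1.67-fold higher. Lamina and chromatin genes were higher in 6 of 15 cases, 9 adjusted over the list alone (adjusted p = 4e-07, and adjusted p = 0.021 with an estimated correlation), with Hmgb2 1.88-fold higher. NF-kB targets were lower in bleomycin in 15 of 30 cases, 18 adjusted over the list alone (adjusted p = 7.7e-19, and adjusted p = 0.019 with an estimated correlation), with Cxcl5 5.87-fold lower. SASP factors were lower in 23 of 56 cases, with 29 lower and 2 higher adjusted over the list alone (adjusted p = 8e-18, and adjusted p = 0.0077 with an estimated correlation). Interferon-stimulated genes were lower in 7 of 28 cases, 13 adjusted over the list alone (adjusted p = 6.1e-12, and adjusted p = 0.093 with an estimated correlation), with Gbp2 2-fold lower and Zbp1 at 2.03 ± 0.567 against 4.35 ± 1.23 FPKM. Fibroblast-like genes were lower in 7 of 16 cases, 9 adjusted over the list alone (adjusted p = 3e-08, and adjusted p = 0.021 with an estimated correlation), with Acta2 2.07-fold and Tagln 2.04-fold lower. Matrix-degrading enzymes were lower in 8 of 19 cases and higher in 2, with 8 and 5 adjusted over the list alone (adjusted p = 0.0021, and adjusted p = 0.13 with an estimated correlation), with Mmp13 1.79-fold and Adamts5 1.52-fold lower.

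Smaller differences between the drugs were found for p53 targets, lower in bleomycin in 7 of 33 cases and higher in 2, with 7 and 3 adjusted over the list alone (adjusted p = 8.2e-05, and adjusted p = 0.071 with an estimated correlation). ATF4 and unfolded protein response genes were higher in 9 of 20 cases, 10 adjusted over the list alone (adjusted p = 0.00097, and adjusted p = 0.13 with an estimated correlation). DNA repair genes were higher in 6 of 32 cases, with 7 higher and 1 lower adjusted over the list alone (adjusted p = 0.0073, and adjusted p = 0.24 with an estimated correlation). Cartilage genes were lower in 3 of 24 cases, among them Prg4, 1.75-fold, and higher in 1, with 4 and 2 adjusted over the list alone (adjusted p = 0.031, and adjusted p = 0.57 with an estimated correlation). This call ended without bleomycin replicate 1 (median 0.02) or doxorubicin replicate 3 (median 0.03), with quantile normalization (-0.04) and with a fit of the compared libraries alone (-0.05). Col2a1 (-0.03 ± 0.10), Acan (-0.04 ± 0.10) and Sox9 (-0.07 ± 0.07) did not pass. Adipocyte markers were lower in bleomycin in 5 of 6 cases, also adjusted over the list alone (adjusted p = 3.6e-10, and adjusted p = 0.003 with an estimated correlation), with Adipoq 3.42-fold and Fabp4 2.41-fold lower. Synovial fibroblast markers were lower in 4 of 5 cases, also adjusted over the list alone (adjusted p = 5.2e-07, and adjusted p = 0.003 with an estimated correlation), with Cd55 1.55-fold and Thy1 1.58-fold lower. Lyz2, of the macrophage list, was 1.79-fold lower. Among the largest differences in the other direction were Msmp, 2.37-fold higher in bleomycin, Smpd3, a sphingomyelinase gene, 2.24-fold and Egr1, an immediate early gene, 2.04-fold. Lysosome genes had 1 higher and 1 lower of 30, also adjusted over the list alone, and neither this list (median 0.04, adjusted p = 0.8) nor the 21 cholesterol synthesis genes (median 0.08, adjusted p = 0.29) were called.

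In all, 1301 genes differed between the drugs, 759 higher and 542 lower in bleomycin, and 51 differed at least 2-fold, 3 higher and 48 lower. Camera called 14 of 26 lists, 8 of them also with an estimated correlation, and fry called 16. The share of higher genes, 58.3%, was 39.7% with median-of-ratios scaling and 46.6% with quantile normalization. The 2-fold count was 136 with a pseudocount of 0.01, a setting in which the calls of Adipoq (log2 difference -1.78), Cfd (-1.97) and Zbp1 (-1.10) ended. The call of Zbp1 also ended with a pseudocount of 0.1 (-1.07), and that of the DNA repair list with a stricter filter (median 0.07).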

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

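The tests of the 3 patterns weighed below were chosen only after the result was seen; the splits of the libraries were planned. Of the 35 splits of the 8 libraries, 1, the real one, gave as many changed genes for bleomycin against vehicle (6086, highest other split 1), for doxorubicin against vehicle (6262, highest other 1), for IL-1β against vehicle (5574, highest other 2) and for bleomycin against doxorubicin (1301, highest other 2). For the drug groups against IL-1β it was 1 of the 100 splits of 12 libraries drawn (7529, highest other 3195). Only the real split reached each of these 5 counts, and 1 of 35 is the smallest share that 35 splits allow. Other splits mix both groups on each side, so fewer calls there follow once the groups differ. The splits say nothing about handling or timing that went with a group.

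A first pattern was 15 NF-kB targets lower in bleomycin than in doxorubicin. Against reads carried over from IL-1β libraries, the levels of Nos2, Vnn3, Saa1 and Saa2 allowed at most 0.058% to 0.24% of IL-1β expression in a doxorubicin library, Saa3 would have needed 0.894% to 3.52%, and 15 of 15 members were still lower after that share was taken out; against 1 doxorubicin library out of place, at least 13 of 15 members were lower without any 1 of them. A larger share of adipocyte-like cells in the doxorubicin cultures stays open: the highest ratio of doxorubicin to bleomycin means of an adipocyte marker (Cfd, 3.7) was exceeded by Saa3 (30.5), Lcn2 (12.5), Cxcl5 (5.87), Il6 (5.65), Cxcl1 (4.8) and Ccl2 (4.26), the members with the highest ratios. Between the lowest doxorubicin and highest bleomycin library 2 of 15 members exceeded 3.7 (Saa3, 11.1, and Lcn2, 6.85) and 13 did not, where Cfd itself had 2.46, Cxcl5 3.33, Cxcl1 3.11, Ccl2 2.82 and Il6 2.34. In doxorubicin Il6 (2.06 FPKM), Cxcl1 (39.5) and Ccl7 (68.5) lay near vehicle (2.08, 38.5 and 67.6). In bleomycin they lay below vehicle (0.364, 8.23 and 22.2). Saa3 (1540 against 156 FPKM), Lcn2 (340 against 78.4) and Cfb (39 against 5.13) stood above vehicle in doxorubicin. Adipoq and Cfd stood at 0.104 and 0.0172 FPKM in vehicle. Continuous exposure to doxorubicin against recovery after bleomycin may also account for the pattern and was not tested. The hyaluronidase pretreatment, listed for bleomycin only, cannot be told apart from the drug here.

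A second pattern was the rise of interferon-stimulated genes in both drug groups. Against scaling between libraries, at least 27 of 28 members were higher in each drug group under 3 other scalings. Against low expression near the pseudocount, at least 27 of 28 members were higher in each drug group with pseudocounts of 0.1 and 0.01, in 27 of 28 every library of both drug groups lay above every vehicle library in FPKM, and 5 of 6 members with a vehicle mean of at least 5 FPKM were higher in both. Longer culture of the drug groups cannot be told apart from the drugs: 25 of 28 members were higher in the drug groups than in IL-1β, but the labels do not state how long the vehicle was cultured. A response to lasting DNA damage may be a biological explanation and was not tested.

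The last pattern was the rise of lysosome genes in all 3 treated groups. Against scaling between libraries, at least 21 of 30 members were higher in each treated group under 3 other scalings, the lowest with a fixed sum in IL-1β, where the median was 0.34. Against 1 vehicle library out of place, at least 28 of 30 members were higher without any 1 of them. A state of all vehicle libraries, such as handling, cannot be told apart from 3 responses, since no other untreated group exists; 2 of 30 members differed between bleomycin and doxorubicin. A response shared by the treatments may be the biological explanation and was not tested.

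In 39 of 556 groups of 4 values tested, 1 library lay far from the other 3, against 27.8 expected by chance at 1 in 20. Doxorubicin replicate 4 did so in 9, each time on the high side: Cxcl1 (61.7 FPKM, others 30.8 to 33), Mmp13 (512, others 286 to 314), Plat (29.3, others 24.6 to 25.3), C3 (58.5, others 37.2 to 40.7), Saa1 (4.64, others 1.48 to 1.79), Nos2 (1.06, others 0.345 to 0.404), Lcn2 (580, others 226 to 279), and the mean log2 values of the SASP list (4.92, others 4.66 to 4.69) and the fibroblast-like list (8.21, others 8.05). Bleomycin replicate 4 did so in 7: Mmp3 (36.5 FPKM, others 24.3 to 26.3), Adamts5 (16.3, others 13.5 to 13.9), C3 (6.57, others 5.07 to 5.13), Npc2 (104, others 95.8 to 97), Shmt2 (75.5, others 85.2 to 86.5), Cd14 (4.83, others 5.63 to 5.77) and the keratinocyte list (1.6, others 1.85 to 1.9).

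In the other libraries the values far from their group were as follows. Vehicle replicate 3 was low for Ube2c (53.3 FPKM), Bub1b (12.8) and Cdkn2c (16.1) and held the only value of Cfd above 0 in its group (0.0689), and vehicle replicate 4 was high for Tyms (16.9). Bleomycin replicate 3 was low for Spp1 (1460) and Panx3 (7.16) and high for the tendon list (3.07), replicate 2 was high for Ccl5 (5.61) and replicate 1 for the skeletal muscle list (1.88). Doxorubicin replicate 3 was high for Sox9 (51.2) and Trp53inp1 (27.7), replicate 2 was low for Cd14 (4.63) and high for the skeletal muscle list (1.91), and replicate 1 was high for the TGF-beta list (5.3). IL-1β replicate 3 was high for Col2a1 (4190) and Ccl5 (45.2) and low for Ccne2 (7.15) and the adipocyte list (2.46), replicate 2 was high for Cytl1 (4.78) and the SASP list (5.47), and replicate 4 was high for Ptx3 (897) and low for the cartilage list (6.22). List values are means of log2(FPKM + 1).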

How the results depend on the processing

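The alternatives were all planned. Named genes kept direction and side of the threshold in 2139 of 2144 tests leaving out 1 library. Under the other settings they did so in 238 of 246 (fixed sum) to 246 of 246 (only the compared libraries). Beyond the 17 fixed genes these were named for large changes here, so agreement was largely built in. Lists kept both in 1119 of 1144 tests without 1 library, 90 of 130 with an estimated correlation, 96 of 130 with fry and 104 of 120 with a mean of at least 5 FPKM. For bleomycin, doxorubicin, IL-1β, drugs against IL-1β and bleomycin against doxorubicin in turn, genes changed at least 2-fold numbered 962, 1278, 1173, 1413 and 123 with a pseudocount of 0.1 and 1019, 1343, 1245, 1478 and 136 with 0.01, where the smaller pseudocount shrinks low values less. They numbered 295, 456, 487 and 548 in the first 4 with a mean of at least 5 FPKM, where fewer genes were tested, and 707, 1540 and 86 in bleomycin, drugs against IL-1β and bleomycin against doxorubicin at a fixed sum (TPM). Lists called with an estimated correlation were 9, 11, 6, 4 and 8, and fry called 24 for drugs against IL-1β. At a fixed sum the direction reversed for Cdkn2a (0.275) and Cdkn2b (0.028) in drugs against IL-1β and for Trp53 in IL-1β (-0.177), where the median of all genes moved by 0.346 and -0.34; for the hypertrophy list in IL-1β (median -0.288) fry gave the opposite direction, and the cause was not tested. Leaving out 1 library, changed genes ranged over 5611 to 5819, 5839 to 6013, 5115 to 5356, 7041 to 7466 and 903 to 1148; 2-fold genes over 447 to 479, 685 to 755, 717 to 759, 886 to 918 and 44 to 55; lists called over 16 to 17, 16 to 17, 14 to 18, 12 to 13 and 13 to 15; and genes shared between bleomycin and doxorubicin, bleomycin and IL-1β, and doxorubicin and IL-1β over 4424 to 4669, 2135 to 2326 and 2238 to 2467. With quantile normalization 44% of changed genes were higher in IL-1β (57.1% in the report) and 46.6% in bleomycin against doxorubicin (58.3%). Whether equal replicate numbers pair the libraries is not stated; 6 of 24 same-number pairs of residuals had r above 0.1 (-0.02 to 0.21, mean 0.071, against -0.024 for other pairs), 13 of 16 libraries correlated best with their own number, and a replicate block gave 6209, 6441, 5735, 7689 and 1488 changed genes. As stated, no count test was run. Depth limits genes near 1 FPKM, where the pseudocount sets the size of a log2 difference.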

Other observations

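The gene groups below were chosen after the data were seen, so their tests have no planned status. Of 16 replication-dependent and linker histone genes, 14 rose with bleomycin (median log2 difference 0.96, adjusted p = 0.0018 with an estimated correlation) and 13 with doxorubicin (median 0.93, adjusted p = 0.0027 with an estimated correlation), while 4 rose and 1 fell with IL-1β (median 0.11, adjusted p = 0.79 with an estimated correlation). H2bc4 stood at 15.4 ± 1.18 FPKM in vehicle, 62.5 ± 1.62 in bleomycin, 68.2 ± 6.42 in doxorubicin and 18.9 ± 2.25 in IL-1β, and H1f2 at 56.4 ± 4.57, 114 ± 8.89, 119 ± 8.84 and 54.8 ± 2.1 FPKM. The libraries were selected for poly(A), and most histone transcripts of this kind lack it.

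Of 19 imprinted genes, 14 fell and 1 rose with IL-1β (median -1.01, adjusted p = 0.0077 with an estimated correlation), while 6 fell and 4 rose with bleomycin and 8 fell and 3 rose with doxorubicin. H19 fell in all 3 treated groups, from 2199 ± 90.9 FPKM to 1445 ± 54.2 in bleomycin, 996 ± 28.8 in doxorubicin and 525 ± 22.8 in IL-1β. Igf2 stood at 2196 ± 58.7 FPKM in vehicle and 1090 ± 54.8 in IL-1β, Mest at 1844 ± 126 and 720.1 ± 51.3, and Peg3 at 241 ± 19 and 97.7 ± 17.4.

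The predicted gene Gm49394, which overlaps Igf2, was listed at 151 to 446 FPKM in vehicle, at most 0.0594 in bleomycin and 0.0883 in IL-1β, and 71.9 in 1 doxorubicin library. Il1b was listed at 0 in all 16 libraries. Xist (7.5 to 17 FPKM) and the Y-linked gene Ddx3y (4.51 to 11.1 FPKM) were present in all 16 libraries. The leukocyte gene Ptprc did not exceed 0.0318 FPKM in any library.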
